A study of Sus scrofa with 24 samples.

How the data were processed

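Messenger RNA of colon mucosa from 24 pigs was sequenced, 16 infected and 8 non-infected. Per the labels' protocols, RNA was taken with a column kit, 500 ng of RNA per sample went into each library, and the libraries were made with a stranded mRNA kit. The deposited files hold raw counts of read pairs per gene, in whole numbers, with no normalization by the authors, per the file headers. The reads were assigned with featureCounts 2.0.0 to the Ensembl release 108 annotation of Sscrofa11.1, per the file headers, whereas the submitters' processing notes name featureCounts 2.0.6. The notes also name HISAT2 2.2.1 and FastQC 0.11.9. Per the file headers, pairs were counted over whole gene records rather than exons, with the reverse-strand setting, so reads from introns and unspliced RNA enter a gene's count and antisense reads do not. The headers set neither of the options that count reads of several places or several genes, so transcripts of near-identical copies and of overlapping genes can be undercounted.

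The files list 35670 genes by Ensembl identifier, of which 13962 had no count in any library. Symbols came from a table of Ensembl identifiers for 15623 genes. A further 1050 were named from NCBI RefSeq's gene table of the same assembly, where a gene covered at least 80% of the other in both directions and no other gene did. That table gives no strand. Among 11486 genes with both names, 95.62% had the same symbol by this overlap. S100A9, MUC5AC, MUC5B, CCL20, IL1B, CD3G, ABCB1, MADCAM1 and SERPINA3-2 were named in this way. The remaining 18997 genes had no symbol and entered the tests by identifier.

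Groups were taken from the treatment label. Libraries held 5413001 to 8883258 counts. No 2 libraries agreed within sampling noise, since over the 276 pairs the smallest chi-square per degree of freedom was 13.3. The labels name separate pigs by number only, and the design text assigns pigs to groups at random. Infected pigs of both stages of the trial are mixed in 1 group, because the labels do not give the stage, so the spread within that group includes any difference between stages.

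Genes were kept with edgeR's filterByExpr at its defaults (a count of about 10 in enough libraries and 15 in all), which left 12681. The main test was edgeR 4.0.16 (R 4.3.3), with TMM scaling and the quasi-likelihood F test of infected against non-infected libraries without covariates. Adjusted p-values are Benjamini-Hochberg values over all genes tested, with a threshold of 0.05. The SE of a log2 fold change is its size divided by the square root of its F. CPM values, counts scaled to a common library size, use TMM-scaled library sizes, and log2 CPM values a prior count of 2. The 37 gene lists were tested with camera of limma 3.58.1 at a preset correlation of 0.01 and again with an estimated correlation, and with fry, which asks whether a list's genes move on balance in 1 direction without comparing them with other genes. A list score is the mean log2 CPM of its measured members in a library. Single values were compared with exact two-sided permutation tests over all 735471 splits of 24 libraries into 16 and 8, and the correlation across the 16 infected libraries with 100000 resamples (scipy 1.17.1).

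The rule for named genes, fixed before the data were examined, took the 10 highest and 10 lowest log2 fold changes among called genes with a symbol, an average log2 CPM of at least 1 and at least 12 of 16 infected libraries on the same side of the control median. It added up to 4 members with the smallest p of each list described, and 12 genes whether or not they passed (CXCL8, IL1B, S100A8, S100A9, LCN2, DUOX2, MUC2, MUC5AC, SLC26A3, AQP8, CA4 and GUCA2A). A list member that this rule would name is not reported here. Of the named genes, F13A1 and SLC3A2 overlap another gene on the same strand over less than 1% of their length. The ratio of summed counts given for thinly counted genes has a 95% Clopper-Pearson interval, which covers counting error only.

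The tests were checked on simulated counts for the 12681 genes with the real library sizes and fitted dispersions and 200 genes changed by known folds. For infected against non-infected pigs, edgeR recovered 82% of the genes raised 2-fold, 64% of those lowered 2-fold and 100% of those changed 4-fold in each direction, and 3.4% of its calls were false. For DESeq2 1.42.0 the false share was 11.9% and for limma-voom, without group weights or a block, 4%. The simulated genes varied independently and with the same dispersion in both groups, without the mixed stages of the real infected group. These shares therefore do not measure the errors of the tests on the real data.

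The alternatives tried were DESeq2, RLE and upper-quartile scaling, leaving out the 20 most abundant genes, no low-count filter, a filter of at least 1 CPM in 8 libraries, robust quasi-likelihood, limma-voom with weights per group, the replicate number as a fixed or random block, and leaving out each library. Chosen after the data were seen were leaving out the 3 infected libraries with a mitochondrial share above 10%, thinning all libraries to the smallest total, the mitochondrial share as a covariate, and exact permutation of list scores.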

Results

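Colon mucosa of pigs given the intestinal spirochaete Brachyspira hyodysenteriae, the agent of swine dysentery, was compared with colon mucosa of pigs that were not given it. The trial held 32 female crossbred piglets of 7 weeks of age. Challenged pigs received 30 mL of broth with 500000000 bacteria per mL by mouth on 3 consecutive days. RNA of 16 infected and 8 non-infected pigs was sequenced, and each library is named here by its group and the number in its library name. According to the design text, challenged pigs were killed either 24 hours after the bacterium was first detected in faeces by qPCR or after 2 days of bloody, mucous diarrhoea. It gives 8 infected pigs to each of these stages, early and acute. The labels do not say which infected library belongs to which stage, so the 16 infected libraries were kept as a single mixed group and no stage was compared.

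The libraries held 5413001 to 8883258 counted read pairs. Infected libraries held 6723075 ± 757868 (SD, n = 16) and non-infected ones 7848739 ± 648790 (SD, n = 8). Chance assignment of the libraries rarely gave as large a difference in mean total (two-sided exact permutation p = 0.00179). Mitochondrially encoded genes took 6.98% ± 3.15 of the counts in infected pigs and 6.99% ± 1.18 in controls (exact permutation p = 0.993). Infected 5, infected 7 and infected 13 had the highest shares, at 15.1%, 11.6% and 10.8%.

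The question put to the data was how the colon mucosa responds to the infection. Transcripts of matrix-degrading enzymes (MMP3, 11.2-fold), the gastric-type mucin MUC5AC (16.1-fold), the leukocyte protein S100A9 (18.7-fold) and the anticoagulant receptor THBD (8.31-fold) were higher in 16 infected than in 8 non-infected pigs, as was the cytokine IL11. The chemokine CCL20 (4.16-fold), the stress-induced factor ATF3 (3.70-fold), the magnesium channel TRPM6 (2.76-fold) and the interferon-linked factor IRF1 (2.17-fold) were lower. Of the 24 fits that each left out 1 library, MMP3, THBD, IL11 and ATF3 were called in 23, S100A9 in 21, MUC5AC in 20, CCL20 in 13, IRF1 in 11 and TRPM6 in 7. Most of these folds are averages over infected libraries that differ, since 10 of the 16 stand apart from the controls on the overall profile described below. Within the control range on that profile lay 6 infected libraries, and of these 0 exceeded all controls for MUC5AC and MMP13, 1 for S100A9 and IL11, 2 for MMP3 and 4 for THBD, while 0 lay below all controls for ATF3, 1 for IRF1 and TRPM6 and 3 for CCL20. The count for ATF3 rests on 1 low control, non-infected 16, and all 16 infected libraries lay below the control median of ATF3. Of 12681 genes tested, 223 were higher and 138 lower in infected pigs, by edgeR's quasi-likelihood test with Benjamini-Hochberg adjustment. At least a 2-fold change was seen in 132 of the higher and 26 of the lower genes. Without adjustment, 2771 genes had a p under 0.05, and the median log2 fold change of all genes was 0.03.

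These counts depended strongly on single libraries. Each of the called genes that could be tested kept its direction in every fit that left out 1 library. That was likely from the start, because the genes were picked for a small p in nearly the same libraries. Leaving out a control gave 6 higher and 6 lower genes without non-infected 11, 26 and 15 without non-infected 13, 37 and 17 without non-infected 9, 79 and 77 without non-infected 16, 86 and 69 without non-infected 2, 93 and 75 without non-infected 15, and 252 and 258 without non-infected 12. Counts fell to 75 and 55 without infected 3, 79 and 55 without infected 6, 91 and 61 without infected 15, 94 and 66 without infected 8, 97 and 65 without infected 1, 106 and 65 without infected 10, 114 and 63 without infected 14, and 119 and 66 without infected 7. They reached 385 and 293 without infected 13, 401 and 277 without infected 12, and 462 and 313 without infected 2. Of the 361 called genes, 11 were called in all 24 of these fits. DESeq2 called 532 higher and 316 lower. Without the 3 infected libraries of high mitochondrial share, a choice made after the data were seen, 379 genes were higher and 306 lower.

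The 10 genes with the highest fold changes under the rule for named genes were led by IL11, a cytokine of the IL-6 family. Its counts summed to 3 over the 8 controls and to 391 over the 16 infected libraries, a ratio of 76.1 after scaling to the totals (95% exact interval 25.8 to 371, counting error only). SERPINA3-2, a protease inhibitor of a multigene family whose copies may share reads, summed to 6 and 546 counts, and 1 infected library held 283 of the latter. S100A9, a calcium-binding protein of neutrophils and monocytes, stood at 8.13 ± 9.51 CPM (SD, n = 16) against 0.434 ± 0.319 (n = 8), a log2 fold change of 4.23 ± 0.93 (SE, adjusted p = 0.0248), and 11 of 16 infected libraries lay above all controls. CEMIP, which degrades hyaluronan, stood at 9.98 ± 10.0 against 0.872 ± 0.595 CPM (adjusted p = 0.0248). CHRDL2, a secreted antagonist of bone morphogenetic proteins, was 10.6-fold higher (adjusted p = 0.0263) and LYPD1 10.3-fold higher (adjusted p = 0.0205). Of 24 leave-one-out fits, LYPD1 was called in 23 and CEMIP and CHRDL2 in 21 each, and SERPINA3-2 in 13 of the 16 that tested it. Leaving out 1 control raised the log2 fold change of LYPD1 to 4.04 (without non-infected 2), of CHRDL2 to 4.02 (without non-infected 15) and of SERPINA3-2 to 6.08 (without non-infected 9). The other 4 were MMP12, MUC5AC, MMP3 and MMP13, described with their groups. On the Sscrofa11.1 assembly, the MMP genes lie together on chromosome 9, with MMP3 (ENSSSCG00000059078) at 33446836 to 33454000, MMP12 (ENSSSCG00000014987) at 33473093 to 33483679 and MMP13 (ENSSSCG00000014988) at 33549008 to 33561162. IL11 (ENSSSCG00000040725) lies on chromosome 6 at 59541213 to 59544896, S100A9 (ENSSSCG00000006588) on chromosome 4 at 96236115 to 96239413 and MUC5AC (ENSSSCG00000033382) on chromosome 2 at 757911 to 790317. Counts cover each whole gene, introns included.

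Among the 10 genes with the lowest fold changes, BTNL2, a butyrophilin-like protein, fell from 11.7 ± 10.99 CPM in controls to 1.53 ± 2.82 in infected pigs (log2 fold change -2.90 ± 0.68 SE, adjusted p = 0.0289), and 14 of 16 infected libraries lay below all controls. CCL20, an epithelial chemokine that attracts lymphocytes and dendritic cells, stood at 10.1 ± 13.03 against 41.6 ± 25.6 CPM (log2 fold change -2.06 ± 0.51, adjusted p = 0.0365). ATF3, a transcription factor induced by stress, was 3.70-fold lower (adjusted p = 0.0205) and below the control median in 16 of 16 infected pigs. RNF152, a ubiquitin ligase, was 2.95-fold lower (log2 fold change -1.56 ± 0.25, adjusted p = 0.00618) in 16 of 16. NAP1L5 was 5.87-fold, PMP22 3.07-fold, PGLYRP2, an amidase of bacterial peptidoglycan, 3.02-fold, TRPM6 2.76-fold, TMEM35A 2.70-fold and RALGDS 2.46-fold lower, with adjusted p between 0.0289 for NAP1L5 and 0.0487 for PGLYRP2. RNF152 was called in all 24 leave-one-out fits, ATF3 in 23, BTNL2, NAP1L5 and RALGDS in 21 each, CCL20 in 13, PMP22 in 9, PGLYRP2 and TMEM35A in 8 each and TRPM6 in 7. Without infected 11 the log2 fold changes of BTNL2 and NAP1L5 were -3.52 and -3.34. CCL20 (ENSSSCG00000016254) lies on chromosome 15 at 129172445 to 129175682, ATF3 (ENSSSCG00000015595) on chromosome 9 at 130772262 to 130785506 and RNF152 (ENSSSCG00000004902) on chromosome 1 at 159530623 to 159601981.

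**Figure D1:**
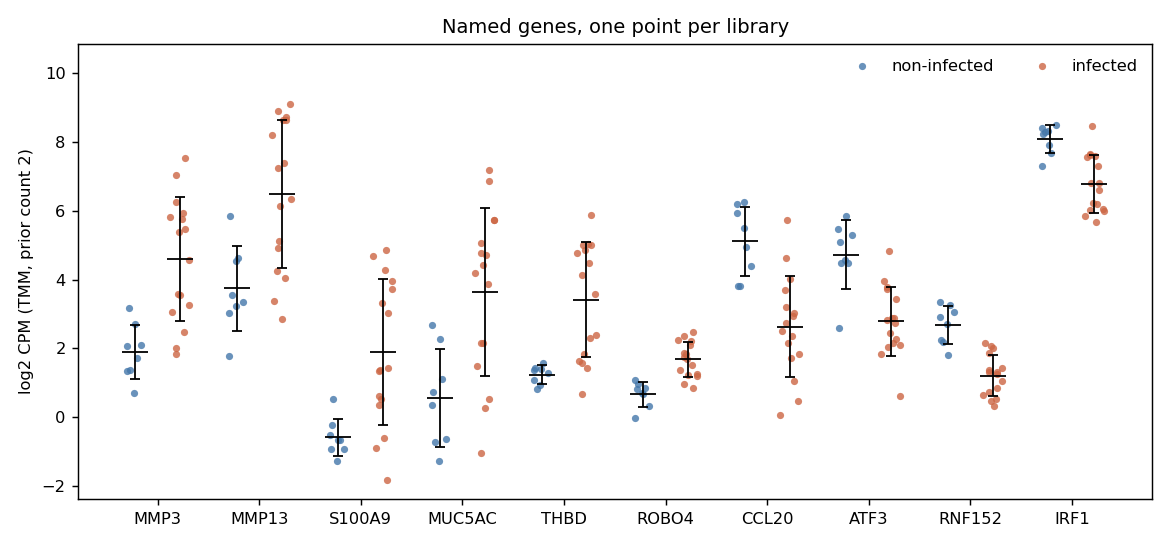
Expression of 10 named genes as log2 CPM in each of the 8 non-infected (blue) and 16 infected (orange) libraries; horizontal bars are group means and error bars are SD. For THBD and ROBO4, 14 of 16 infected libraries lie above all controls, whereas for MMP13 the infected libraries spread from control levels upwards. For S100A9, 11 of 16 lie above all controls. Infected 4 lies below them with 0 counts, where the lowest control count is 1, so its position carries little weight.

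Genes were then grouped by 37 lists fixed before the data were examined, and 35 lists with at least 3 measured members were tested with camera at a preset inter-gene correlation of 0.01. Camera called 4 lists higher and 8 lower in infected pigs. None of these 12 calls held with an estimated correlation, where the smallest adjusted p was 0.449, and up to 19 lists were called in a random split of the same libraries. An exact two-sided permutation test of each list's mean log2 CPM per library, added after the data were seen and adjusted over the 35 lists, called 3 lists, all higher, which were matrix remodelling, endothelial markers and gastric-type mucins. The smallest adjusted fry p was 0.0507.

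Matrix remodelling genes were higher in infected pigs, with 8 of 18 measured members called higher, 0 lower and 10 not past the test, and 10 higher when adjusted over the list alone. The median log2 fold change was 0.97 (camera adjusted p = 7.87e-05, adjusted p = 0.449 with an estimated correlation). MMP13, a collagenase, stood at 196 ± 195 CPM against 18.2 ± 17.3 (log2 fold change 3.42 ± 0.81, adjusted p = 0.0295). MMP1, another collagenase, was 9.24-fold higher (adjusted p = 0.0248), the stromelysin MMP3 11.2-fold (adjusted p = 0.0205) and the macrophage elastase MMP12 18.7-fold (adjusted p = 0.0324). They were called in 23 (MMP3), 22 (MMP1), 20 (MMP13) and 19 (MMP12) of 24 leave-one-out fits, and without non-infected 15 the log2 fold change of MMP12 was 4.84. The mean list score was 3.20 ± 0.79 in infected pigs (SD, n = 16) and 2.16 ± 0.32 in controls (n = 8), with 10 of 16 infected libraries above all controls (exact permutation p = 0.00227, adjusted 0.0397). Of these 10, 9 are among the 10 libraries above the control range on the first principal component, described below, and the 6 infected libraries inside that range scored 2.101 to 2.908 against 1.71 to 2.802 in controls, so the higher list score was not common to all infected pigs. Fibroblast and smooth muscle marker scores differed by 0.29 and -0.42 on the same scale, with adjusted exact permutation p-values of 0.486 and 0.336.

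Endothelial markers had 3 of 11 members called higher and 0 lower, with 9 higher when adjusted over the list alone (median log2 fold change 0.84, camera adjusted p = 2.4e-06, adjusted p = 0.449 with an estimated correlation). ROBO4, a receptor that stabilises vessels, was 2.29-fold higher (log2 fold change 1.2 ± 0.24, adjusted p = 0.0205) and above the control median in 16 of 16 infected pigs. ESAM, a junction protein of endothelium, was 2.05-fold higher (adjusted p = 0.0425) and KDR, the main receptor for VEGF, 1.95-fold (adjusted p = 0.0479). FLT1, another VEGF receptor, had a log2 fold change of 0.92 ± 0.28 (adjusted p = 0.0656). The list score was 2.59 ± 0.48 against 1.92 ± 0.33 (exact permutation p = 0.00189, adjusted 0.0397), with 9 of 16 infected libraries above all controls, 7 of them among the 10 above the control range on the first principal component. Of 6 endothelial adhesion molecules, MADCAM1, which binds gut-homing lymphocytes, was called higher (2.44-fold, adjusted p = 0.0425) and 5 did not pass. Of 24 leave-one-out fits, ROBO4 was called in 23, ESAM in 11, MADCAM1 in 10 and KDR in 6.

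Of 6 gastric-type mucin and foveolar genes, 2 were called higher and 4 did not pass over all genes, whereas 4 were higher when adjusted over the list alone. MUC5AC, a gel-forming mucin typical of stomach and airway, stood at 32.4 ± 42.0 CPM against 1.96 ± 2.19 (log2 fold change 4.01 ± 0.94, adjusted p = 0.0289), with 10 of 16 infected libraries above all controls. The trefoil peptide TFF2 was 7.30-fold higher (adjusted p = 0.0494). TFF1 and MUC5B had log2 fold changes of 4.37 ± 1.31 and 1.70 ± 0.53 and did not pass (adjusted p = 0.0618 and 0.0717). MUC5AC was called in 20 of 24 leave-one-out fits and TFF2 in 7. The log2 fold change of TFF2, 2.87, was 2.06 with group weights in limma-voom and 1.85 in the 16 libraries that share their numbers. Among the infected libraries of that subset, 2, 11, 12 and 13 lay inside the control range on the first principal component. The others, 8, 9, 15 and 16, lay above it. The subset thus holds a larger share of libraries inside that range than the whole infected group, which limits its smaller sizes here and below. The median log2 fold change of the gastric-type mucins and foveolar genes was 2.28, and 0.99 without the low-count filter and 1.309 in those 16 libraries. Camera gave the list an adjusted p of 0.0513, with adjusted p = 0.449 with an estimated correlation, and the score test an adjusted exact permutation p of 0.0429. The 10 infected libraries with a list score above all controls were the same 10 that lay above the control range on the first principal component, and the other 6 scored 1.042 to 1.99, inside the control range of 0.778 to 2.219. Goblet cell products had 1 of 16 members called higher, SPINK4 (2.48-fold, adjusted p = 0.0463, called in 7 of 24 leave-one-out fits), and 4 when adjusted over the list alone. MUC2, the main colonic mucin, stood at 92.1 ± 68.5 against 60.1 ± 29.9 CPM and did not pass (adjusted p = 0.372). SPDEF and BEST2 had log2 fold changes of 1.10 ± 0.32 and 2.97 ± 0.98 (adjusted p = 0.0537 and 0.0852), and without non-infected 16 that of BEST2 was 3.61.

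Inflammatory cytokines and chemokines moved in both directions. Of 16 measured, 3 were called higher, 1 lower and 12 did not pass, with 4 higher and 1 lower when adjusted over the list alone. PTGS2, the inducible prostaglandin synthase, stood at 15.2 ± 16.0 against 1.93 ± 1.53 CPM (adjusted p = 0.0417), and CSF3, the granulocyte growth factor, at 1.77 ± 1.41 against 0.446 ± 0.329 (adjusted p = 0.0477). IL11 was the other higher gene and CCL20 the lower. PTGS2 was called in 12 of 24 leave-one-out fits and CSF3 in 8 of the 16 that tested it. CXCL8, a neutrophil chemokine, stood at 19.6 ± 15.1 against 24.8 ± 9.48 CPM (log2 fold change -0.33 ± 0.38, adjusted p = 0.637), and IL1B at 2.52 ± 1.48 against 1.36 ± 0.695 (adjusted p = 0.168). Camera did not call the list, and its median log2 fold change of 0.19 has no settled sign. The median of the inflammatory cytokines and chemokines was -0.003 without infected 10, -0.047 in the 16 libraries that share their numbers, compared without pairing, and 0.616 over 23 genes without the low-count filter.

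Of 6 measured neutrophil markers, S100A9 was called higher and 5 did not pass, among them CSF3R with a log2 fold change of 0.80 ± 0.37 (adjusted p = 0.204). S100A8, the partner of S100A9, was removed by the low-count filter, with 9 counts over the controls and 378 over the infected libraries, 10 of 16 above all controls by count. Without the filter its log2 fold change was 4.34 (adjusted p = 0.0297). The filter decides how the neutrophil markers look as a list: their median log2 fold change was 0.191 over the 6 genes that passed it, 0.799 over 9 genes at 1 CPM in 8 libraries and 1.652 over 15 genes without a filter. Among the genes removed, picked here after their values were seen, S100A12 had 15 counts over the controls and 358 over the infected libraries (log2 fold change without the filter 3.58, adjusted p = 0.0444) and the chemokine receptor CXCR2 14 and 123 (2.23, adjusted p = 0.0607). Epithelial antimicrobial genes had 2 of 17 members called higher and 0 lower, and 3 higher when adjusted over the list alone. REG4, a secreted lectin, stood at 2364 ± 1601 against 689 ± 306 CPM (adjusted p = 0.0425), and S100A9 was the other. REG4 was called in 9 of 24 leave-one-out fits. CHI3L1 had a log2 fold change of 1.87 ± 0.59 (adjusted p = 0.0746). The antimicrobial siderophore-binding protein LCN2 stood at 11.4 ± 12.6 against 5.25 ± 3.51 CPM (adjusted p = 0.25) and the hydrogen peroxide source DUOX2 at 248 ± 125 against 243 ± 75.7 CPM (adjusted p = 0.966).

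Complement and coagulation genes had 3 of 18 members called higher and 0 lower, and 5 higher when adjusted over the list alone. Thrombomodulin, THBD, which turns thrombin to an anticoagulant role, stood at 17.7 ± 16.5 against 2.11 ± 0.421 CPM (log2 fold change 3.06 ± 0.62, adjusted p = 0.0205), and 14 of 16 infected libraries lay above all controls. F13A1, a clot-stabilising factor, was 5.42-fold higher (adjusted p = 0.0352) and tissue factor, F3, 3.79-fold (adjusted p = 0.0435). The log2 fold change of F13A1, 2.44, was 1.73 with group weights in limma-voom and 1.78 in the 16 libraries that share their numbers, and that of THBD 2.31 with group weights. Of 24 leave-one-out fits, THBD was called in 23, F13A1 in 15 and F3 in 6. The urokinase gene PLAU had a log2 fold change of 1.02 ± 0.30 (adjusted p = 0.0577).

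Interferon-gamma response genes lay lower in infected pigs, with 2 of 22 members called lower, 0 higher and 20 not past the test, and 14 lower when adjusted over the list alone. Their median log2 fold change was -0.97 (camera adjusted p = 1.14e-11, adjusted p = 0.449 with an estimated correlation). The list score was 4.59 ± 1.07 against 5.85 ± 0.66, and 10 of 16 infected libraries lay below all controls (exact permutation p = 0.00715, adjusted 0.05, not below the threshold). These 10 were the same 10 libraries that lay above the control range on the first principal component, described below; infected 9, at 4.640, lay just under the lowest control at 4.645. The other 6 infected libraries, at 5.044 to 6.511, did not lie below the control range of 4.645 to 6.436, so the lower list score was not common to all infected pigs. IRF1, a transcription factor of the response, averaged 279 ± 70.7 CPM in controls and 129 ± 81.9 in infected pigs (adjusted p = 0.0424), where the 6 libraries inside the control range of the first component lay at 7.29 to 8.47 log2 CPM against 7.3 to 8.49 in controls and the other 10 below all controls. The tryptophan tRNA ligase WARS1 fell from 190 ± 85.7 to 104 ± 44.4 CPM (adjusted p = 0.0435), and IRF1 and WARS1 were called in 11 and 9 of 24 leave-one-out fits. The GTPase GBP1 had a log2 fold change of -1.58 ± 0.50 and did not pass (adjusted p = 0.0746). Of 23 type I interferon-stimulated genes 0 were called, and 0 when adjusted over the list alone, with a median of -0.50 (camera adjusted p = 2.87e-07, adjusted p = 0.6 with an estimated correlation). That median of the type I interferon-stimulated genes was -1.095 with group weights in limma-voom and 0.081 in the 16 libraries that share their numbers, compared without pairing, the only 1 of 38 alternatives with the other sign, and -1.032 without infected 11, -0.289 without non-infected 15 and -0.308 without non-infected 9; 9 of 16 infected libraries had a list score below all controls. The 16 libraries that share their numbers include infected 11 and infected 12, which had the highest type I interferon scores, 7.987 and 6.897. STAT2, DDX60, IFI44L and IFIH1 had log2 fold changes of -0.63, -1.32, -0.78 and -0.58.

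T and NK cell markers had 0 of 19 members called and a median log2 fold change of -0.45, or -0.817 with group weights in limma-voom, -0.693 without infected 5 and -0.774 without the 3 infected libraries of high mitochondrial share (camera adjusted p = 0.000161, adjusted p = 0.695 with an estimated correlation). Their score was 3.24 ± 1.03 against 3.98 ± 0.50 (exact permutation p = 0.072), with the same 10 infected libraries below all controls, and the T-cell receptor subunits CD3D and CD3G had log2 fold changes of -0.64 ± 0.34 and -0.73 ± 0.39. The log2 fold change of KLRK1 was -0.72 ± 0.46. Pattern recognition and NF-kB genes had 1 of 22 members called lower and the same number when adjusted over the list alone (median -0.26, camera adjusted p = 0.00193, adjusted p = 0.449 with an estimated correlation). That gene was BIRC3, an inhibitor of apoptosis, at 109 ± 49.1 against 209 ± 55.5 CPM (adjusted p = 0.0289, called in 21 of 24 leave-one-out fits). The inflammasome parts CASP1 and PYCARD and the flagellin receptor TLR5 had log2 fold changes of -0.89, -0.81 and -0.64 (adjusted p = 0.1, 0.102 and 0.15).

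Mature colonocyte markers had 1 of 21 members called lower, TRPM6, and 2 lower when adjusted over the list alone (median -0.33, camera adjusted p = 0.000161, adjusted p = 0.6 with an estimated correlation). TRPM6 stood at 9.10 ± 7.64 against 25.0 ± 11.8 CPM (adjusted p = 0.0428, called in 7 of 24 leave-one-out fits). The list's median was -0.706 with group weights in limma-voom, -0.512 without infected 16, -0.494 without the 3 infected libraries of high mitochondrial share and -0.156 in the 16 libraries that share their numbers. The list score lay below all controls in 8 infected libraries, all among the 10 above the control range on the first principal component, and the 6 inside that range scored 7.126 to 7.888 against 7.05 to 8.053 in controls. The surface keratin KRT20 stood at 1733 ± 805 against 3129 ± 553 CPM (adjusted p = 0.0545), the chloride exchanger SLC26A3 at 485 ± 488 against 1224 ± 533 (adjusted p = 0.159), and the peptide hormone GUCA2A at 335 ± 352 against 738 ± 294 (adjusted p = 0.167). In the other direction lay the carbonic anhydrase CA4, at 282 ± 301 against 81.7 ± 49.97 CPM (adjusted p = 0.0976). The water channel AQP8 stood at 154 ± 213 against 102 ± 65.0 (adjusted p = 0.709). The bile acid transporter subunit SLC51A had a log2 fold change of -1.17 ± 0.47 (adjusted p = 0.144).

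Ion and water transport genes had 2 of 25 members called lower, 0 higher and 23 not past the test, with 2 lower and 2 higher when adjusted over the list alone. The sodium-proton exchanger SLC9A2 fell from 89.5 ± 38.3 to 40.0 ± 20.9 CPM (adjusted p = 0.0365), and the mineralocorticoid receptor NR3C2 from 38.2 ± 10.5 to 23.6 ± 7.71 (adjusted p = 0.0479), each below the control median in 16 of 16 infected pigs and called in 14 and 8 of 24 leave-one-out fits. AQP3 and the sodium channel subunit SCNN1G had log2 fold changes of 0.89 ± 0.27 and 3.21 ± 0.999 (adjusted p = 0.0615 and 0.0714), and without non-infected 11 that of SCNN1G was 3.81. This list's median was positive, at 0.10, and -0.053 at its lowest alternative, whereas camera's direction was down, without a call.

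Endoplasmic reticulum stress genes had 0 of 17 members called higher and 1 lower, ATF3, whereas 9 were higher and 1 lower when adjusted over the list alone (median 0.36, camera adjusted p = 0.00186, adjusted p = 0.6 with an estimated correlation). That median was 0.231 with the replicate number as a fixed block. DDIT3, ASNS and ATF4 had log2 fold changes of 0.56 ± 0.16, 0.77 ± 0.22 and 0.26 ± 0.10 (adjusted p = 0.0537, 0.0537 and 0.141). Plasma cell markers had 0 of 11 members called, and 4 higher and 1 lower when adjusted over the list alone (median 0.49, camera adjusted p = 0.00467, adjusted p = 0.49 with an estimated correlation), and MZB1 and IRF4 had log2 fold changes of 1.001 ± 0.373 and 0.90 ± 0.35. TNFRSF13B and DERL3 had values of 0.66 ± 0.24 and 0.35 ± 0.13. Xenobiotic genes had 1 of 10 members called lower, TIPARP, a target of the aryl hydrocarbon receptor (1.59-fold lower, adjusted p = 0.0456, called in 7 of 24 leave-one-out fits), and 2 when adjusted over the list alone. Their median was -0.32 (camera adjusted p = 0.00542, adjusted p = 0.449 with an estimated correlation), and the efflux pump ABCB1 had a log2 fold change of -1.08 ± 0.37. Cholesterol synthesis had 0 of 20 called and a median of -0.26 (camera adjusted p = 0.00467, adjusted p = 0.755 with an estimated correlation), with HMGCS1 at -0.59 ± 0.21. Fatty acid and butyrate oxidation had 0 of 25 called and a median of -0.12 (camera adjusted p = 0.0237, adjusted p = 0.695 with an estimated correlation), with ACAT1 at -0.28 ± 0.10 and PDK4 at 2.29 ± 0.71, or 1.49 without infected 2. Neither of these lists had a member called when adjusted over the list alone.

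Several sizes above depended on the fit. With group weights in limma-voom the log2 fold change was 3.69 for IL11 (main 5.74), 3.49 for SERPINA3-2 (5.47), 3.38 for MMP12 (4.23), 2.80 for S100A9 (4.23), 3.33 for MUC5AC (4.01), 2.77 for MMP3 (3.49), 2.62 for CEMIP (3.48), 2.75 for MMP13 (3.42), 2.56 for MMP1 (3.21), 2.26 for PTGS2 (2.96) and -4.16 for BTNL2 (-2.90). Genes not called moved in the same way, with 3.12 for TFF1, 2.04 for BEST2, 1.16 for PDK4, 1.13 for CA4, -2.16 for SLC26A3, -2.02 for DDX60 and -1.32 for KLRK1. Limma-voom with the replicate number as a random block, which used no group weights, gave nearly the same sizes. These were 3.68 for IL11, 2.78 for S100A9 and -4.16 for BTNL2. The shifts in size given with group weights, here and above, therefore go with limma-voom and not with the weights. In the 16 libraries that share their numbers, compared without pairing, BTNL2 stood at -2.20 and BEST2 at 2.28. With the mitochondrial share as a covariate MMP12 stood at 3.54 and TFF1 at 3.75, and in DESeq2 TFF1 stood at 3.47. Among the list medians, those of xenobiotic genes (-0.087), fatty acid and butyrate oxidation (-0.041), pattern recognition and NF-kB genes (-0.14) and plasma cell markers (0.322) shrank in those 16 libraries. Cholesterol synthesis stood at -0.144 without non-infected 16, and neutrophil markers, with 1 library left out at a time, ran from 0.075 without infected 5 to 0.645 without non-infected 9.

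**Figure D2:**
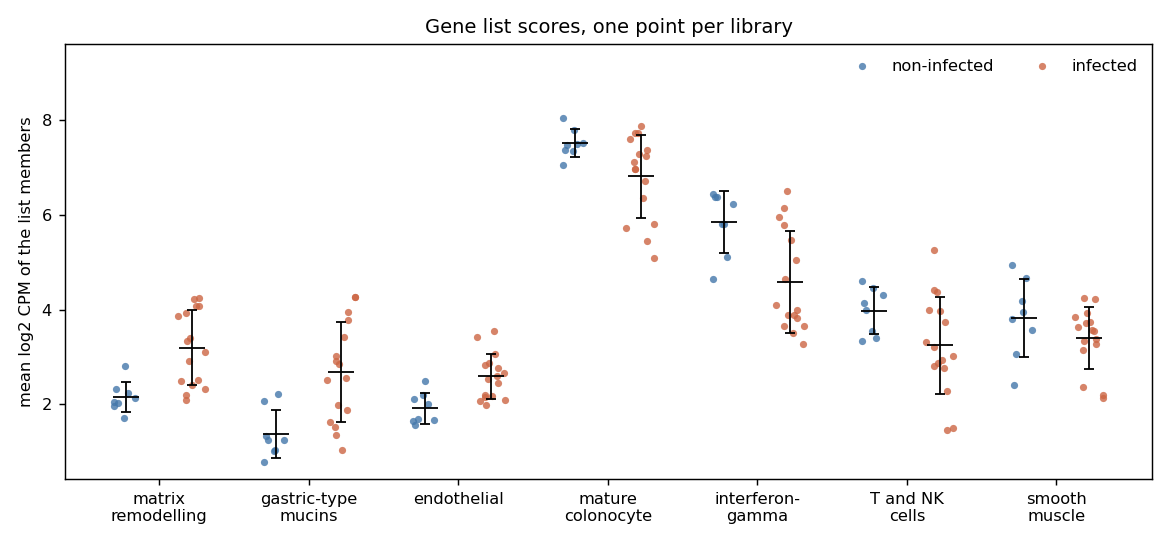
Mean log2 CPM of the members of 7 gene lists in each of the 8 non-infected (blue) and 16 infected (orange) libraries; horizontal bars are group means and error bars are SD. Matrix remodelling scores are 3.20 ± 0.79 in infected pigs against 2.16 ± 0.32 in controls, and interferon-gamma scores are 4.59 ± 1.07 against 5.85 ± 0.66.

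The groups were also compared on their overall profiles. On the first principal component of the 500 most variable genes, which held 50.5% of their variance, infected libraries averaged 9.3 ± 24.3 (SD, n = 16) and non-infected ones -18.5 ± 6.4 (SD, n = 8). Chance assignment of the libraries rarely gave a difference as large as this one, 27.8 (two-sided exact permutation over 735471 splits, p = 0.00575). Of the 16 infected libraries, 10 lay above the control range of -28.1 to -7.7 and 6 lay inside it. Many list scores followed this division. Besides the lists for which this is given above, the libraries among these 10 made up all 9 of the infected libraries below all controls for type I interferon-stimulated genes, 10 of 11 for pattern recognition and NF-kB genes, 7 of 7 for xenobiotic genes and 8 of 9 for fatty acid and butyrate oxidation, and, above all controls, 10 of 11 for endoplasmic reticulum stress and 9 of 9 for hypoxia and glycolysis. The group means of these lists therefore average over infected libraries that differ. The called genes named in this text followed the division to different degrees. Of 44, 6 had 0 of the 6 infected libraries inside the component's range beyond all controls (MUC5AC, MMP13, TFF2, F3, ATF3 and NR3C2), 28 had 1 or 2, and 10 had 3 or more, among them ROBO4, TMEM35A, TRAK2 and SLC3A2 with 5 each. For ATF3 this rests on non-infected 16, at 2.59 log2 CPM, with the nearest control at 4.47. Infected 11, 13, 2, 4 and 5 stood at 3.96, 2.88, 2.82, 2.74 and 3.72, and infected 12 at 4.83. The fall of ATF3 was thus not limited to the 10 libraries above the component's range. The component is itself built from variable genes, so the overlap of its division with lists and genes describes the libraries and tests nothing. The 2 sets of infected libraries were not compared. Infected libraries also lay farther from their group's centroid. The distance over all tested genes was 61.8 ± 10.5 in infected pigs and 49.1 ± 4.6 in controls (two-sided exact permutation p = 0.00405). Infected libraries were shallower, and the shallowest of them lay far out. Infected 5, 7, 2 and 13 held 5413001, 5450828, 5854345 and 6063708 counts and lay at 82.4, 67.6, 75.3 and 69.2. Infected 10 and 1, with 6768109 and 6844951 counts, lay at 72.6 and 70.1. Infected 5, 7 and 13 also had the highest mitochondrial shares. The part of depth or mitochondrial share in the wider spread therefore stays open.

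**Figure D3:**
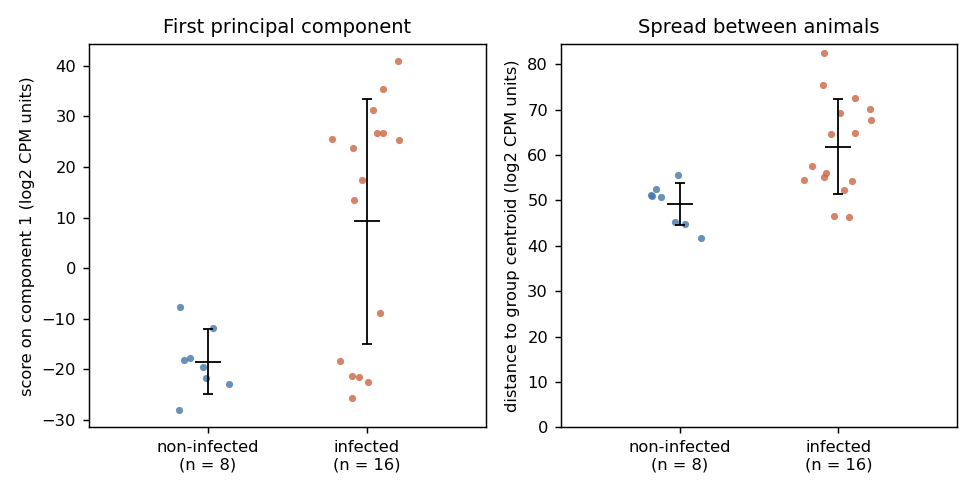
Left, the score of each library on the first principal component; right, the distance of each library to the centroid of its group, in log2 CPM units; horizontal bars are group means and error bars are SD. The 8 controls lie between -28.1 and -7.7 on the component, and 10 of 16 infected libraries lie above that range.

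Whether pigs with more neutrophil transcripts had fewer colonocyte transcripts was tested across the 16 infected libraries. The scores of the 6 neutrophil and 21 colonocyte markers were not related there (Pearson r = 0.014, permutation p = 0.958, Spearman rho = -0.026, permutation p = 0.927, adjusted p = 0.958 for each). Without the 2 libraries farthest from the median neutrophil score, r was 0.287. The neutrophil score holds only the markers that passed the low-count filter, without S100A8, S100A12 and CXCR2. A relation with neutrophil transcripts as a whole is therefore not excluded. In the 8 controls r was 0.749 (exact permutation p = 0.029) and rho 0.762 (exact permutation p = 0.0368), neither past the threshold after adjustment over these 4 coefficients (adjusted p = 0.0736 for each).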

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

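The tests of the interferon-gamma pattern against T and NK cells and against 1 high control, and both tests of the matrix pattern, were chosen after the result was seen. The 128 values given for the 8 controls (library totals, list scores, component scores and named genes) were searched for a library far from the others. Chance alone gives such a library in about 1 of 20 groups, and 3 were found. ATF3 stood at 2.59 log2 CPM in non-infected 16, with the nearest control at 4.47. TFF1 stood at 1.10 in non-infected 15, with the nearest at -0.65, and without that library the TFF1 log2 fold change was the highest of all leave-out fits, at 6.48. The hypoxia and glycolysis score stood at 6.12 in non-infected 9, with the nearest at 5.95. The infected group, with 16 libraries, was not searched in this way.

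Whether chance assignment of the libraries gives as many calls was tested with 100 splits into 16 and 8, the real one included. The real split called 361 genes and the highest other split 294, so 1 of 100 splits, the real one, gave as many. That is the smallest share that 100 splits can give, so chance is unlikely but not excluded. The same held for higher genes (223 against 192, 1 of 100), lower genes (138 against 102, 1 of 100) and genes at least 2-fold higher (132 against 111, 1 of 100). For genes at least 2-fold lower, 2 of 100 splits gave as many, with 26 in the real split and 38 in the highest other. Chance is unlikely there too, but not excluded. For the 12 lists called by camera, chance cannot be called unlikely: 45 of 100 splits called as many, and the highest other called 19. Camera called the interferon-gamma response list in 51 of the other 99 splits, so its call alone says little. As small a camera p for this list was reached in 3 of 100 splits, but the list was picked because its p was the smallest of all lists. A test added after these values were seen therefore counted the splits in which any list reached as small a p. These were 23 of 100, at a -log10 p of 12.5 in the real split and 29.2 in the highest other. Chance cannot be called unlikely for this list either.

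In the first pattern, 10 of 16 infected libraries lay beyond the control range on the first principal component. Infected libraries were shallower, yet 10 still lay beyond the range after thinning all libraries to the smallest total. After each gene's linear trend on the mitochondrial share was removed, 12 lay beyond it. After removal of the trend on the smooth muscle score, 10 did, which argues against different amounts of muscle as the whole cause. The stage of infection, which the design names and the labels do not assign, stays open and was not tested.

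In the second pattern, interferon-gamma response genes lay lower in infected pigs. The list score lay below all controls in 10 infected libraries, the same 10 as in the first pattern, and the other 6 did not lie below the control range. These 2 patterns are therefore not independent, and whether the fall goes with infection as such or with what sets those libraries apart stays open. Fewer T and NK cells may lower transcripts that these cells carry. The interferon-gamma score lay lower even relative to the T and NK marker score (difference 1.34 ± 0.56 against 1.87 ± 0.40, exact permutation p = 0.0274). This bears only on an equal fall of both scores, so loss of T and NK cells stays open. Without any 1 control the list's median log2 fold change was at most -0.907, so a single high control does not account for it, and after thinning it was -0.953. The adjusted p of the list score was 0.05, not below the threshold, and chance was not excluded for its camera call, so a lower interferon-gamma response in infected mucosa is not established here.

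In the third pattern, matrix remodelling genes were higher. This pattern is not separate from the first either: of the 10 infected libraries with a list score above all controls, 9 are among the 10 of the first pattern. Relative to the mean of the fibroblast and smooth muscle scores, the matrix score was -1.04 ± 0.81 in infected pigs and -2.15 ± 0.59 in controls (exact permutation p = 0.00276). These 2 marker scores differed by 0.29 and -0.42, in opposite directions, so subtracting their mean hardly changed the matrix difference. More submucosa in infected samples is therefore not excluded, whereas the muscle markers showed no rise. Relative to monocyte and macrophage markers the matrix score was -0.16 ± 1.34 against -1.67 ± 0.45 (exact permutation p = 0.00679). That marker score alone was 3.36 ± 0.81 against 3.83 ± 0.57, so subtracting it could only widen the difference. The markers thus showed no larger number of macrophages. Raised expression of these enzymes per cell could not be told apart from a change in the kind of stromal cell or macrophage, and neither was tested. What sets the 10 libraries of the first pattern apart also stays open.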

How the results depend on the processing

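Leaving out the 3 libraries of high mitochondrial share, thinning, the mitochondrial covariate and the permutation of list scores were chosen after the data were seen. All 361 called genes that an alternative could test kept their direction in each alternative run. The genes were picked from the same libraries, so this was likely from the start. The number past the threshold did not hold. Leaving out 1 library at a time gave 6 to 462 higher and 6 to 313 lower genes, and at least 2-fold, 3 to 208 higher and 2 to 66 lower, against 223, 138, 132 and 26. DESeq2 called 532 higher and 316 lower, of which at least 2-fold 223 and 49. Without a low-count filter, which tests 21708 genes, there were 113 and 89. Limma-voom with group weights called 446 lower, 153 of them at least 2-fold, against 312 higher. Without the 3 libraries of high mitochondrial share, the counts were 379 and 306, and 201 and 80 at least 2-fold; with that share as a covariate, 240 were lower, 55 of them at least 2-fold. RLE (219 and 139), upper-quartile scaling (280 and 135), leaving out the 20 most abundant genes (210 and 172), 1 CPM in 8 libraries (239 and 145), robust fitting (202 and 132) and thinning (173 and 138) stayed within 1.5 times. The filter of 1 CPM in 8 libraries, planned as the stricter, kept more genes (13164). Except where the construction shows it, the cause was not tested.

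The 8 control numbers recur among the infected libraries, and the design text says that controls were killed in parallel with challenged pigs, but no label says that a number marks such a pair. Deviations of same-numbered libraries correlated at -0.157 to 0.283, over 0.1 in 2 of 8 pairs, and 1 of 8 controls correlated best with its own number. The data therefore do not show a pairing. They do not exclude one either, since wide differences among infected libraries could mask a modest shared effect. With the number as a fixed replicate block, 4 genes were higher (4 at least 2-fold) and 0 lower (0 at least 2-fold), with 1066 genes at an unadjusted p under 0.05, and 8 lists were called higher. The same 16 libraries without pairing gave 0 higher and 0 lower, and 0 and 0 at least 2-fold, with 1048 genes at an unadjusted p under 0.05 in edgeR. Among their infected libraries, 2, 11, 12 and 13 lay inside the control range on the first principal component, and 8, 9, 15 and 16 above it. The median of the type I interferon-stimulated genes was -0.515 with the fixed block and 0.081 in the same 16 libraries without pairing. With the fixed block, the log2 fold change was 1.16 for F13A1 (main 2.44), 1.46 for TFF2 (2.87), 2.31 for MMP13, 2.2 for THBD, 2.58 for MMP1, 2.32 for PTGS2 and 0.60 for CA9 (1.22). As a random block in limma, the number gave 83 higher (24 at least 2-fold) and 206 lower (84 at least 2-fold).

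Camera with an estimated correlation called 0 lists higher and 0 lower, against 4 and 8; permutation of list scores called 3 and 0; leaving out 1 library gave 4 to 7 and 7 to 11. The component and spread differences kept their direction and side of the threshold in their 3 alternatives each, and the correlation passed the threshold in none of its 3 alternatives (0.009 to 0.378). Over the named genes, the 44 called ones kept their call in 1135 fits and lost it in 502, with no reversal. The 44 others gained a call in 123 fits and reversed in 13, all for DUOX2 and AQP8. The AQP8 log2 fold change was -1.04 with group weights and -1.02 with the random block. The DUOX2 log2 fold change, at 0.03, lay between -0.07 and 0.11 when 1 library was left out, and was 0 without a filter, -0.09 with group weights, -0.08 with the random block, and below 0 without non-infected 11, 12 or 2 or infected 10, 12, 16, 2 or 5. Genes near 1 CPM rest on about 5 to 9 counts per library, which limits low genes such as IL11 and S100A8.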

Other observations

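Several gene groups showed few or no called members. Hypoxia and glycolysis had 1 of 20 measured members called higher, CA9, a carbonic anhydrase of hypoxic cells (2.33-fold, adjusted p = 0.045, called in 8 of 24 fits that left out 1 library), and 1 higher and 1 lower when adjusted over the list alone. Its glycolytic regulator PFKFB4 had a log2 fold change of -0.86 ± 0.25 (adjusted p = 0.0545). Tuft cell markers had 1 of 8 called, PTGS1, the constitutive prostaglandin synthase (2.18-fold higher, adjusted p = 0.0494, called in 8 of those fits), and 2 higher and 1 lower when adjusted over the list alone. For 13 further lists no member was called over all genes. Median log2 fold changes were 0.40 for fibroblast, -0.47 for smooth muscle, -0.27 for monocyte and macrophage, -0.17 for B cell, -0.15 for mast cell and eosinophil, -0.10 for enteroendocrine and 0.14 for crypt stem cell markers. They were 0.13 for cell cycle genes, -0.06 for tight junctions and desmosomes, -0.02 for the IL-17 and IL-22 axis, -0.05 for oxidative phosphorylation and 0.04 for ribosomal proteins. Mitochondrially encoded genes had a median of 0.08, with 0 of 13 called and camera's direction down. Several of these small medians changed sign in at least 1 of 38 alternatives and have no settled direction: over them, B cell markers ran from -0.388 to 0.299, mast cell and eosinophil markers from -0.24 to 0.139, monocyte and macrophage markers from -0.461 to 0.02, crypt stem cell markers from -0.049 to 0.2, cell cycle genes from -0.029 to 0.181, tight junctions and desmosomes from -0.103 to 0.058, the IL-17 and IL-22 axis from -0.058 to 0.06, ribosomal proteins from -0.042 to 0.137 and mitochondrially encoded genes from -0.294 to 0.143. The fibroblast median was 0.608 without non-infected 8, and the smooth muscle median -0.26 without non-infected 11 and -0.259 without non-infected 15. The enteroendocrine median was -0.204 without infected 7 and -0.054 without infected 6. In these lists, 3 fibroblast markers were higher when adjusted over the list alone. The 2 measured erythroid and platelet markers had a median of 0.60 and were not tested as a list. Without the low-count filter that median was 0.338 over 11 genes. No enteric neuron or glia marker passed the filter.

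The smallest adjusted p in the table, 0.00618, belonged to 4 genes with modest folds, of which 3 were named only after their values were seen. HACE1, a ubiquitin ligase, stood at 29.8 ± 4.97 against 49.5 ± 9.58 CPM, TRAK2, which links mitochondria to motor proteins, at 16.1 ± 4.28 against 31.4 ± 8.24, and SLC3A2, the heavy chain of amino acid exchangers, at 38.9 ± 8.43 against 22.2 ± 3.73. With RNF152, they were on the same side of the control median in 16 of 16 infected pigs and were called in all 24 fits that left out 1 library.

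On the first principal component the infected libraries lay in 2 stretches with no library between -9.0 and 13.5. Infected 5 lay at -25.8, infected 13 at -22.5, infected 12 at -21.5, infected 2 at -21.3, infected 11 at -18.5 and infected 4 at -9.0, within the control range of -28.1 to -7.7. Infected 9 lay at 13.5, infected 14 at 17.4, infected 8 at 23.7, infected 7 at 25.4, infected 6 at 25.6, infected 3 at 26.7, infected 16 at 26.8, infected 15 at 31.3, infected 10 at 35.5 and infected 1 at 40.9. Their interferon-gamma response scores were 6.143 in infected 5, 5.483 in infected 13, 6.511 in infected 12, 5.796 in infected 2, 5.952 in infected 11 and 5.044 in infected 4, and then, in the order just given, 4.640 in infected 9, 3.880 in infected 14, 3.656 in infected 8, 3.660 in infected 7, 4.091 in infected 6, 3.893 in infected 3, 3.832 in infected 16, 3.511 in infected 15, 4.001 in infected 10 and 3.273 in infected 1, against 4.645 to 6.436 in the controls. The libraries in these stretches were not compared with each other.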
